A study of Arabidopsis thaliana with 48 samples.

How the data were processed

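The deposited processed values are estimated counts of 48 libraries, produced per the submitters' processing notes with Trimmomatic 0.36, FastQC and kallisto 0.43.1 against TAIR10. Of the estimated counts 7.80 percent were not whole numbers, and all were rounded. The 48 columns of TPM were not used. For 1 alternative test TPM were computed from the rounded counts and the effective lengths given with them. A duplicate of the table with comma decimals was left out because it holds the same values apart from rounding of very small ones. The table lists 33602 targets, 1 per locus, of which 32835 (97.7 percent) matched loci of the reference annotation. Of 22901 multi-exon loci compared, 74.0 percent had a target length closer to the gene span with introns than to any spliced transcript. Only 0.69 percent had the length of a spliced transcript. Transcript levels in the text are counts on these targets. Targets are 33323 nuclear, 133 chloroplast and 146 mitochondrial. Raw reads were not analysed here.

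Differential expression was tested with edgeR 4.0.16 (quasi-likelihood F test, TMM normalization, filterByExpr), with the 24 libraries of an organ in 1 fit of 8 group coefficients. The organ difference was fitted on the 12 Col-0 libraries. P-values were adjusted by Benjamini-Hochberg over all loci tested, with a threshold of 0.05. The fits tested 21697 loci in shoots, 21954 in roots and 22301 for the organ difference, with common biological coefficients of variation of 0.129, 0.101 and 0.118. There were 29 comparisons, of which 22 were pairwise and 7 were interactions. Gene lists, 18 in number, were tested with camera at a preset correlation of 0.01 and again with an estimated correlation, and members were also adjusted over their list alone. Other tools were limma 3.58.1, DESeq2 1.42.0, R 4.3.3, Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

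Groups, comparisons, gene lists, the alternatives and the rule for naming genes were fixed before the data were examined. By that rule the text names EIL1 and EIL3, any member of the OAS cluster, sulfate transport and sulfate assimilation lists, the 10 largest changes in each direction among loci past the threshold with at least 5 CPM in the higher group and no overlap of libraries, and up to 4 members with the smallest p-values from each other list. Alternatives were RLE size factors, no count filter, DESeq2, a replicate block, only the groups compared in the fit, limma-trend on log2(TPM + 1), and each library left out in turn. Total-count scaling, and giving root counts without the first Col-0 +S or eil1-labelled +S library beside the others, were chosen after seeing the data. Results were taken as moved where a count changed by more than a factor of 1.5. The pipeline was tested on simulated data with 200 changed loci, and it recovered 86.36 percent of 2-fold changes in shoots, 96.97 percent in roots and 75.76 percent for the organ difference. Of 1.5-fold changes it recovered 60.61, 71.21 and 16.67 percent, so simulated changes of that size were often missed, most of all for the organ difference. The real comparisons called up to 13198 loci, many more than were changed in the simulation. No interaction of genotype with sulfate was simulated. These rates need not hold for the real comparisons.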

Results

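RNA was sequenced from shoots and roots of 18-day-old Arabidopsis seedlings of 4 genotypes: wild-type Col-0, a T-DNA line in EIL1 (AT2G27050), a T-DNA line in EIL3 (AT1G73730) and the double mutant eil3 eil1. EIL1 is a transcription factor of ethylene signalling, and EIL3, also known as SLIM1, is a transcription factor known for its part in the response to sulfur limitation. Seedlings grew with 0.75 mM magnesium sulfate (+S) or with 0.015 mM (-S), and each of the 16 groups had 3 libraries. The -S medium also held 0.75 mM magnesium chloride and the +S medium 0 mM, so low sulfate and added chloride came together. Shoot libraries held 27029088 to 37809216 estimated counts and root libraries 26615772 to 38269946. The comparisons ask what low sulfate changes in each organ of the wild type, and which parts of that response differ in the mutant lines. Levels are mean CPM (TMM-scaled) ± SD of 3 libraries, changes are log2 fold changes ± SE, and a locus rose or fell where edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over all loci passed the threshold. The SE was derived from that test, as the absolute log2 fold change divided by the square root of the F value, and is approximate. Estimated counts of near-identical copies, among them LSU1 and LSU2, MAM1 and MAM3, CYP79F1 and CYP79F2, and AOC1 and AOC2, are uncertain because reads can be shared between them. Each comparison within a group of 6 libraries rests on 3 against 3. Replicates are numbered as the deposited table's columns, and in shoots these numbers cannot be tied to single samples because the sample titles hold other numbers.

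EIL1 transcript was clearly reduced only in the libraries labelled as the double mutant. In shoots at +S it stood at 102 ± 3.57 CPM in Col-0, 83.98 ± 5.06 in the eil1-labelled libraries, 109 ± 3.18 in the eil3-labelled libraries and 45.6 ± 2.78 in the eil3 eil1-labelled libraries. At -S the shoot levels were 105 ± 5.14, 92.4 ± 5.98, 94.9 ± 12.7 and 26.96 ± 1.12 in the same order. In roots EIL1 stood at 51.4 ± 1.46, 51.4 ± 2.25, 53.6 ± 0.672 and 15.8 ± 2.52 CPM at +S and at 55.9 ± 4.28, 42.95 ± 5.72, 52.4 ± 3.94 and 19.5 ± 2.15 at -S. The eil1-labelled libraries differed from Col-0 by edgeR in roots at -S alone (log2 -0.38 ± 0.10, edgeR quasi-likelihood adjusted p = 0.0406), and that call was lost without any 1 of the 3 Col-0 -S replicates or of the eil1-labelled -S replicates 1 and 2, with only the groups compared in the fit, and with limma-trend on TPM. The edgeR adjusted p was 0.0796 in shoots at +S, where DESeq2 called EIL1 lower (log2 -0.28, adjusted p = 0.0345), 0.277 in shoots at -S and 0.998 in roots at +S. In the eil3 eil1-labelled libraries EIL1 was lower than in Col-0 in all 4 comparisons, from log2 -1.16 ± 0.08 in shoots at +S to -1.96 ± 0.082 in shoots at -S.

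EIL3 transcript did not follow the labels in shoots. It stood at 17.02 ± 0.954 CPM in Col-0 and 17.2 ± 2.81 in the eil3-labelled shoots at +S, and at 21.9 ± 1.41 and 19.2 ± 2.57 at -S. In the eil3 eil1-labelled shoots it was higher than in Col-0, by log2 0.81 ± 0.11 at +S and 0.45 ± 0.11 at -S. In roots it was lower in the eil3-labelled libraries than in Col-0, by log2 -0.57 ± 0.10 at +S and -0.59 ± 0.10 at -S. The eil3 eil1-labelled roots held 21.6 ± 1.85 CPM at +S and 21.2 ± 1.09 at -S, against 23.5 ± 1.08 and 22.2 ± 0.649 in Col-0. A locus-level count does not show where along a transcript its reads lie, so a T-DNA line can keep reads of part of its gene. Because the targeted transcripts do not separate the single mutants from Col-0 in both organs, genotypes are given throughout as labelled. The labels do not say whether the single lines and the double mutant carry the same alleles, so a difference between a single line and the double mutant cannot be assigned to 1 of the 2 genes.

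**Figure D1:**
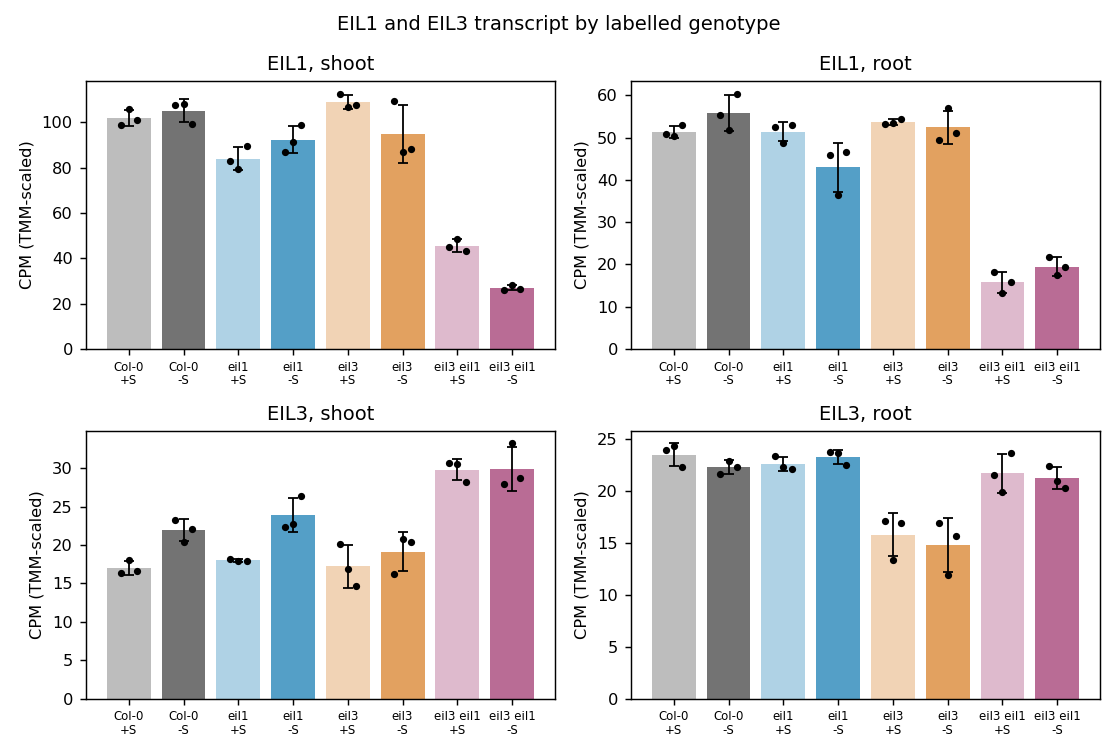
EIL1 and EIL3 transcript in shoots and roots of each labelled genotype at +S (pale bars) and -S (dark bars), in TMM-scaled CPM. Bars are means, error bars SD and points the 3 libraries of a group. EIL1 lies lowest in the eil3 eil1-labelled groups.

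In Col-0 shoots, low sulfate raised the genes of the O-acetylserine (OAS) cluster, a set of co-regulated sulfur-deficiency genes. All 7 of its 7 members rose (7 adjusted over the list alone), with a median log2 change of 5.30. SDI1 (AT5G48850), a repressor of glucosinolate synthesis, went from 1.09 ± 0.230 to 931 ± 204 CPM (log2 9.75 ± 0.25). GGCT2;1 (AT5G26220), an enzyme of glutathione breakdown, rose by 7.40 ± 0.26 and APR3, an adenosine phosphosulfate reductase, by 4.31 ± 0.19. Sulfate transporters rose for 6 of 11 measured members and fell for 1 (6 and 2 adjusted over the list alone). SULTR1;1 (AT4G08620), a root uptake transporter, rose by 4.66 ± 0.31 to 25.1 ± 3.94 CPM, and SULTR4;2 (AT3G12520), a vacuolar exporter, rose by 3.97 ± 0.14. Of 20 sulfate assimilation genes 11 rose and 3 fell (11 and 3 adjusted over the list alone). APR1 rose by 3.61 ± 0.17 and SERAT3;2 (AT4G35640), a serine acetyltransferase, by 5.35 ± 0.27. ATPS4, an ATP sulfurylase, fell by 2.63 ± 0.14 and ATPS2 changed by -0.86 ± 0.11.

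Aliphatic glucosinolate genes moved the other way in Col-0 shoots. These genes make sulfur-containing defence compounds from methionine, and 19 of 21 fell (19 adjusted over the list alone), with a median of -2.39. BCAT4, the entry enzyme of side-chain elongation, went from 131 ± 36.1 to 4.42 ± 2.72 CPM (log2 -4.90 ± 0.33). CYP83A1 changed by -2.45 ± 0.21 and FMO-GS-OX1 by -3.64 ± 0.32. Among 12 indolic glucosinolate genes 5 rose and 1 fell (5 and 1 adjusted over the list alone), and the member that fell was CYP79B3 (-1.22 ± 0.18). Of 11 glucosinolate breakdown genes 3 rose and 3 fell (4 and 3 adjusted over the list alone). BGLU28, a beta-glucosidase linked to glucosinolate breakdown, rose by 10.18 ± 0.45 to 808 ± 238 CPM, and the myrosinase TGG2 changed by -2.65 ± 0.26. MGL, methionine gamma-lyase, rose by 3.46 ± 0.29.

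Jasmonate genes rose for 9 of 13 members in Col-0 shoots (9 adjusted over the list alone). LOX2, a lipoxygenase of jasmonate synthesis, reached 2125 ± 124 CPM from 195 ± 41.03 (log2 3.44 ± 0.22), and TAT3 rose by 1.84 ± 0.22. All 17 nuclear photosynthesis genes fell (17 adjusted over the list alone), with a median of -0.75. LHCA1, a light-harvesting protein, changed by -0.75 ± 0.12 and RCA, rubisco activase, by -0.98 ± 0.14. NYE1, a gene of chlorophyll degradation, rose by 1.64 ± 0.079. In all, 7570 of 21697 loci changed, 3677 higher and 3893 lower at -S. The camera test with its preset correlation passed for the OAS cluster, sulfate transport, sulfate assimilation, aliphatic glucosinolates, jasmonate and photosynthesis. With an estimated correlation the photosynthesis call was lost (adjusted p = 0.178 with an estimated correlation), while that of aliphatic glucosinolates held (adjusted p = 0.0142 with an estimated correlation). Scaling by total counts, which shifts the median of all loci by 0.12, gave 5711 higher and 2453 lower.

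In Col-0 roots, low sulfate raised sulfate uptake genes and lowered glucosinolate synthesis genes. All 7 OAS cluster genes rose (7 adjusted over the list alone; median 3.27), and SDI1 went from 11.8 ± 2.23 to 1139.9 ± 164 CPM (log2 6.59 ± 0.23). Sulfate transporters rose for 7 of 12 members and fell for 1 (8 and 1 adjusted over the list alone). SULTR1;1 (AT4G08620) went from 6.98 ± 1.56 to 192 ± 30.9 CPM (log2 4.77 ± 0.22). The other high-affinity uptake transporter, SULTR1;2 (AT1G78000), rose by 1.93 ± 0.12 to 933 ± 70.5 CPM. SULTR2;1 (AT5G10180), a vascular transporter of root-to-shoot transport, went from 25.2 ± 2.34 to 418 ± 26.4 CPM (log2 4.05 ± 0.18). Of 20 assimilation genes 8 rose and 5 fell (8 and 7 adjusted over the list alone), with SERAT3;2 (AT4G35640) up by 5.03 ± 0.23 and ATPS4 changed by -2.81 ± 0.094; the camera call of this list was lost with an estimated correlation (adjusted p = 0.0846 with an estimated correlation).

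Of 19 aliphatic glucosinolate genes measured in roots 18 fell and 1 rose in Col-0 (18 and 1 adjusted over the list alone), with a median of -1.72. BCAT4 (AT3G19710) went from 344 ± 27.1 to 16.7 ± 1.92 CPM (log2 -4.37 ± 0.16). MAM1, a methylthioalkylmalate synthase, changed by -4.01 ± 0.13. Of 12 indolic glucosinolate genes 7 fell (9 adjusted over the list alone), among them CYP79B3 (-3.37 ± 0.14) and CYP79B2 (-2.32 ± 0.11), which open the pathway from tryptophan. BGLU28 rose by 9.92 ± 0.65 to 836 ± 251 CPM. In all, 1982 of 21954 root loci changed, 935 higher and 1047 lower at -S, and 1902 (901 and 1001) without Col-0 +S replicate 1, a library doubted after the data were seen. The camera calls of the OAS cluster, sulfate transport, aliphatic and indolic glucosinolates held with an estimated correlation.

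The organs differed in the size of the response. The low-sulfate change of roots minus that of shoots passed the interaction test for 2948 of 22301 loci, 1332 positive and 1616 negative. All 7 OAS cluster genes had the smaller change in roots (7 adjusted over the list alone), with a difference of -3.16 ± 0.30 for SDI1 and -1.81 ± 0.16 for SHM7, a serine hydroxymethyltransferase. Of 20 assimilation genes 10 had a negative and 1 a positive difference (11 and 1 adjusted over the list alone), as for APR1 (-2.77 ± 0.14). SULTR2;1 (AT5G10180) had the opposite sign (4.41 ± 0.17), and its shoot level was 112 ± 18.3 CPM at +S and 87.8 ± 7.37 at -S. Of 12 indolic glucosinolate genes 9 had a negative difference (9 adjusted over the list alone), with CYP79B3 at -2.15 ± 0.23. VSP2, a jasmonate-responsive storage protein, had a difference of -1.66 ± 0.17. The camera calls of the OAS cluster, assimilation and indolic glucosinolate lists held with an estimated correlation. Without Col-0 +S root replicate 1 the count was 2317. Scaling by total counts shifted the median of all loci by -0.12 and gave 918 positive and 2604 negative differences.

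**Figure D2:**
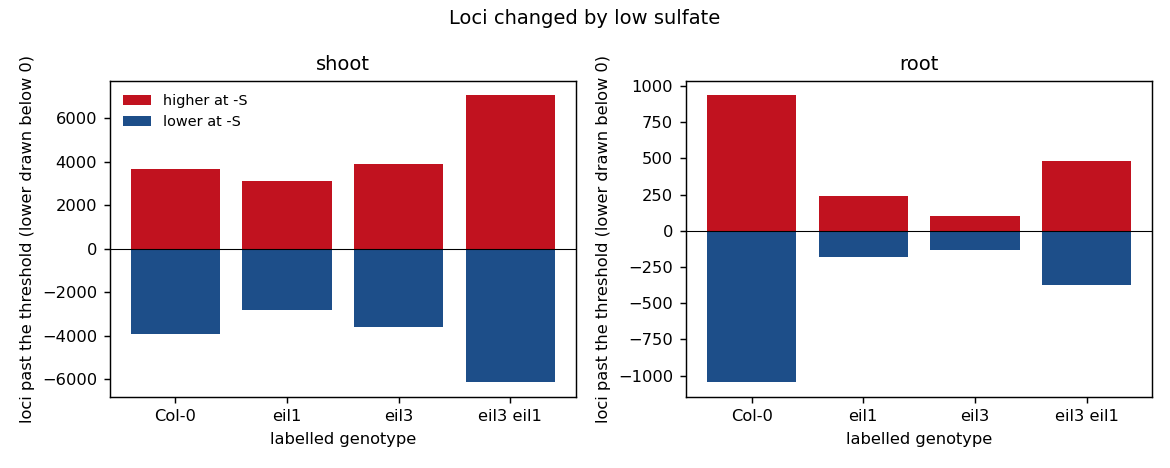
Number of loci past the threshold at -S against +S in each labelled genotype, for shoots (left) and roots (right). Loci higher at -S are drawn above 0 and loci lower at -S below it. Shoots of the eil3 eil1-labelled genotype had the most loci and eil3-labelled roots the fewest.

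In roots, the induction of sulfate-deficiency genes was smaller in each mutant-labelled genotype than in Col-0. All 7 OAS cluster genes rose in all 4 genotypes (7 adjusted over the list alone in each), with medians of 3.27 in Col-0, 2.38 in the eil1-labelled roots, 2.09 in the eil3-labelled roots and 1.71 in the eil3 eil1-labelled roots. The interaction with genotype was negative for 6 of 7 in the eil1-labelled, 5 in the eil3-labelled and 7 in the eil3 eil1-labelled roots (7, 6 and 7 adjusted over the list alone). At -S SDI1 reached 417 ± 101, 325 ± 34.4 and 159 ± 21.5 CPM in the same order, with interactions of -1.75 ± 0.27, -2.78 ± 0.27 and -4.26 ± 0.27. For SHM7 they were -1.10 ± 0.12, -1.66 ± 0.12 and -2.29 ± 0.12. The camera call of the OAS cluster held with an estimated correlation in each interaction.

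Sulfate transporters responded less than in Col-0 in the roots of all 3 mutant-labelled genotypes. The median interaction of the list was -0.59 in the eil1-labelled, -0.77 in the eil3-labelled and -0.90 in the eil3 eil1-labelled roots, and all 3 camera calls held with an estimated correlation (adjusted p = 0.0171, 4.00e-05 and 2.18e-05). Whether the eil1-labelled differed from the eil3-labelled roots was not tested. The interaction was negative for 5 of 12 transporters in the eil3-labelled and for 6 in the eil3 eil1-labelled roots (7 and 7 adjusted over the list alone). In the eil1-labelled roots 1 transporter had a negative interaction over all loci and 5 adjusted over the list alone. SULTR1;1 (AT4G08620) at -S stood at 31.2 ± 1.94 CPM in the eil3-labelled and 16.7 ± 3.65 in the eil3 eil1-labelled roots, against 192 ± 30.9 in Col-0 (interactions -2.26 ± 0.30 and -3.31 ± 0.30). SULTR1;2 (AT1G78000) had interactions of -1.15 ± 0.17 and -1.63 ± 0.17. SULTR2;1 (AT5G10180) was already higher than in Col-0 at +S, by 1.71 ± 0.17 in the eil3-labelled and 2.37 ± 0.17 in the eil3 eil1-labelled roots, and its interactions were -2.92 ± 0.23 and -3.07 ± 0.23. Among the assimilation genes, SERAT3;2 (AT4G35640) had interactions of -2.78 ± 0.39 and -3.60 ± 0.42. ATPS4, which fell in Col-0 roots, had positive ones (1.30 ± 0.12 and 2.17 ± 0.12). BGLU28 at -S reached 15.003 ± 1.69 and 11.04 ± 1.44 CPM in the eil3-labelled and eil3 eil1-labelled roots, against 836 ± 251 in Col-0 (interactions -6.01 ± 1.21 and -7.15 ± 1.03), and the call in the eil3-labelled roots was lost without their +S replicate 1 and without their +S replicate 2.

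The loss of glucosinolate transcripts at low sulfate was smaller in mutant-labelled roots as well. BCAT4 at -S stood at 57.7 ± 15 CPM in the eil1-labelled, 78.5 ± 9.71 in the eil3-labelled and 220.0 ± 18.3 in the eil3 eil1-labelled roots, against 16.7 ± 1.92 in Col-0. Its interactions were 1.70 ± 0.20, 2.08 ± 0.20 and 3.53 ± 0.20, and those of CYP79B3 were 1.83 ± 0.19, 2.24 ± 0.19 and 3.17 ± 0.19. Of 19 aliphatic glucosinolate genes 3, 5 and 18 had a positive interaction in the eil1-labelled, eil3-labelled and eil3 eil1-labelled roots (14, 15 and 18 adjusted over the list alone). A single member had a negative interaction in the latter pair of genotypes (1 and 1 adjusted over the list alone). Of 12 indolic genes 5, 5 and 6 had a positive interaction (5, 6 and 7 adjusted over the list alone). The camera calls of both lists held with an estimated correlation in all 3 interactions. Low sulfate changed 422, 233 and 855 loci in these genotypes, and 84, 207 and 840 loci passed the interaction test.

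Counts of loci in roots depended on single libraries. For the low-sulfate response of the eil1-labelled roots the count was 238 without +S replicate 1 and 266 without -S replicate 2, and for that of the eil3-labelled roots 142 without +S replicate 1. For the eil3 eil1-labelled roots it was 520 and 477 without +S replicates 1 and 2 and 486 without -S replicate 1. The interaction of the eil1-labelled roots fell to 53 and 49 loci without Col-0 +S replicates 2 and 3, to 37 without Col-0 -S replicate 3, and to 49 and 47 without the eil1-labelled +S replicate 2 and -S replicate 2. That of the eil3 eil1-labelled roots was 526 without its +S replicate 2. Without Col-0 +S replicate 1 the 3 interactions had 89, 216 and 934 loci, and without the eil1-labelled +S replicate 1 that of the eil1-labelled roots had 61. The photosynthesis genes summed to 2894 CPM in the eil1-labelled +S root replicate 1 and to 804 and 1061 in the other replicates of that group. In that genotype 4 of 17 photosynthesis genes had a negative low-sulfate change (16 adjusted over the list alone; camera adjusted p = 0.213 with an estimated correlation). In the eil3 eil1-labelled roots the list moved up instead, from a sum of 754 ± 122 CPM at +S to 1099 ± 146 at -S. With the preset correlation the camera adjusted p was 1.13e-05 for that response and 0.00133 for its interaction. Whether these calls hold with an estimated correlation is not given here. With scaling by total counts the eil3 eil1-labelled interaction had 394 positive and 427 negative loci, against 506 and 334.

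**Figure D3:**
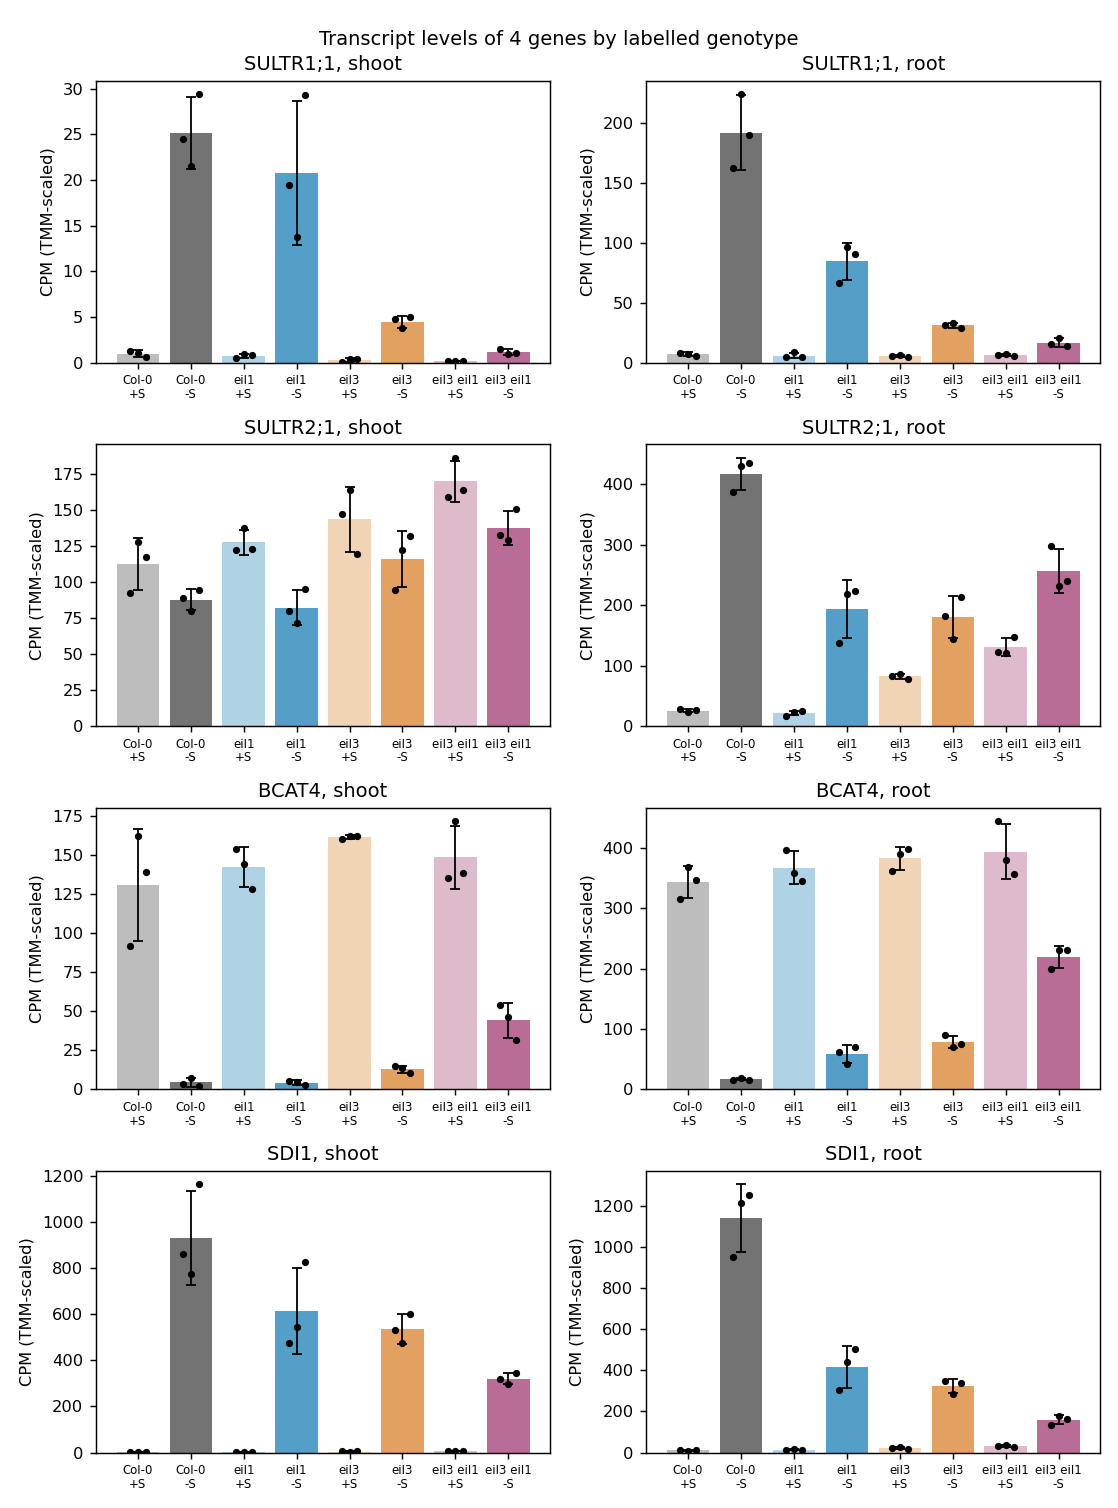
CPM of SULTR1;1, SULTR2;1, BCAT4 and SDI1 in shoots (left) and roots (right) of each labelled genotype at +S (pale bars) and -S (dark bars). Bars are TMM-scaled means, error bars SD and points the 3 libraries of a group. In roots at -S, SDI1 and SULTR1;1 lie lower and BCAT4 higher in the eil3 eil1-labelled group than in Col-0.

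Set directly against Col-0 at -S, the mutant-labelled roots differed at 551 (eil1-labelled), 1459 (eil3-labelled) and 2651 loci (eil3 eil1-labelled). OAS cluster genes were lower for 6, 7 and 7 of 7 members (7 in each adjusted over the list alone). Aliphatic glucosinolate genes were higher for 15, 16 and 18 of 19 (16, 18 and 18 adjusted over the list alone), and 0, 1 and 1 members were lower. MAM1 was higher by 1.92 ± 0.13, 2.15 ± 0.13 and 3.53 ± 0.13. SULTR1;1 (AT4G08620) was lower by -1.18 ± 0.18 in the eil1-labelled roots. PYD4, an enzyme of beta-alanine metabolism, differed from Col-0 by -4.58 ± 0.17 in the eil3-labelled and -4.96 ± 0.17 in the eil3 eil1-labelled roots. GGCT2;1 (AT5G26220) differed by -1.58 ± 0.20, -2.99 ± 0.21 and -3.48 ± 0.22. Photosynthesis genes, which mark green tissue, were lower by camera in the eil1-labelled and eil3-labelled roots (adjusted p = 0.00052 and 4.83e-05 with the preset correlation). Whether the calls hold with an estimated correlation is not given here. In the eil3 eil1-labelled roots they did not pass (camera adjusted p = 0.662). Their summed levels were 863 ± 116, 776 ± 111 and 1099 ± 146 CPM, against 1106 ± 168 in Col-0. The eil1-labelled count was 253 and 216 without Col-0 -S replicates 2 and 3 and 187 without the eil1-labelled -S replicate 1, and the eil3-labelled count was 938 without Col-0 -S replicate 3.

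At +S the mutant-labelled roots differed from Col-0 at 272, 480 and 193 loci. APR2 differed by -0.82 ± 0.067 in the eil3-labelled and -1.03 ± 0.067 in the eil3 eil1-labelled roots, and SULTR4;2 (AT3G12520) by -0.96 ± 0.10 and -1.22 ± 0.10. SDI1 was higher by 1.42 ± 0.20 in the eil3 eil1-labelled roots. NRT2.4, a nitrate transporter, was lower by -1.68 ± 0.29 in the eil3-labelled roots. The aliphatic glucosinolate list was higher by camera in the eil3-labelled and eil3 eil1-labelled roots, with medians of 0.15 and 0.15 (adjusted p = 0.00109 and 0.000827, and 0.479 and 0.486 with an estimated correlation). By the edgeR test 0 of its 19 genes differed in any of the 3 comparisons (0 adjusted over the list alone), 0, 5 and 4 had an unadjusted p below 0.05, and DESeq2 called 0 in each. Photosynthesis genes, which mark green tissue, were lower by camera in the eil3-labelled and eil3 eil1-labelled roots (adjusted p = 0.000108 and 2.69e-11, and 0.48 and 0.486 with an estimated correlation). Their summed levels were 867 ± 91.8 and 754 ± 122 CPM, against 1204 ± 129.6 in Col-0. With only the groups compared in the fit the 3 counts were 135, 250 and 325, with the replicate block 345, 605 and 349, and with DESeq2 572, 828 and 467, so their order depended on the fit. Without Col-0 +S replicate 1 they were 398, 389 and 147. The eil1-labelled count was 52 and 98 without Col-0 +S replicates 2 and 3, and 83 and 75 without the eil1-labelled +S replicates 1 and 2. The eil3-labelled count was 193 without Col-0 +S replicate 2 and 110 without the eil3-labelled +S replicate 3. The eil3 eil1-labelled count was 115 and 99 without Col-0 +S replicates 2 and 3, and 114, 65 and 86 without its own +S replicates 1, 2 and 3. Scaling by total counts gave 271 higher and 215 lower loci in the eil3-labelled roots, against 189 and 291, and 142 and 73 in the eil3 eil1-labelled roots, against 98 and 95.

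In shoots, all 7 OAS cluster genes also rose in every genotype (7 adjusted over the list alone in each), with medians of 5.30 in Col-0, 4.90 in the eil1-labelled, 3.71 in the eil3-labelled and 2.92 in the eil3 eil1-labelled shoots. The smaller change in the eil3-labelled genotypes came with higher levels at +S, and for SDI1 also with lower levels at -S. GGCT2;1 (AT5G26220) stood at 2.44 ± 0.431 CPM in Col-0 at +S, 32.1 ± 4.71 in the eil3-labelled and 55.01 ± 8.89 in the eil3 eil1-labelled shoots, and its interactions were -4.46 ± 0.30 and -6.05 ± 0.30. SDI1 had interactions of -2.91 ± 0.30 and -4.43 ± 0.29. At -S its libraries held 475 to 601 CPM in the eil3-labelled and 296 to 345 in the eil3 eil1-labelled shoots, against 774 to 1162 in Col-0. The interaction was negative for 5 and 6 of the 7 OAS genes in the eil3-labelled and eil3 eil1-labelled shoots (6 and 6 adjusted over the list alone) and for 4 and 8 of 11 sulfate transporters (4 and 8). SULTR4;2 (AT3G12520) had interactions of -2.38 ± 0.18 and -3.55 ± 0.18, and SULTR2;2 (AT1G77990) of -1.44 ± 0.16 and -2.46 ± 0.16. Jasmonate genes had a negative interaction for 7 and 9 of 13 (8 and 9 adjusted over the list alone), with LOX2 at -2.24 ± 0.28 and -2.91 ± 0.28. The camera calls of these 3 lists held with an estimated correlation in both interactions.

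The eil3 eil1-labelled shoots changed most. Low sulfate changed 7570 loci in Col-0, 5917 in the eil1-labelled, 7516 in the eil3-labelled and 13198 in the eil3 eil1-labelled shoots. The interaction passed for 8009 loci in the eil3 eil1-labelled shoots (4336 positive, 3673 negative), 386 in the eil3-labelled and 5 in the eil1-labelled shoots. With only the groups compared in the fit the low-sulfate counts were 6767, 6147, 4947 and 12586 in the order given. The interaction counts were then 7835, 143 and 3. Photosynthesis genes fell further in the eil3 eil1-labelled shoots: the interaction was negative for 15 of 17 (16 adjusted over the list alone; camera adjusted p = 0.183 with an estimated correlation). LHCB3 stood at 1013 ± 86.2 CPM at -S, against 3629 ± 318 in Col-0 (interaction -1.64 ± 0.21). Aliphatic glucosinolate genes fell less, with a positive interaction for 14 of 21 (16 adjusted over the list alone; camera adjusted p = 0.402 with an estimated correlation), as for BCAT4 (3.15 ± 0.41). NAC044, a NAC transcription factor, reached 66.8 ± 8.78 CPM at -S against 1.12 ± 0.228 in Col-0 (interaction 5.85 ± 0.46). Flavonoid and anthocyanin genes had a positive interaction for 7 of 14 (8 adjusted over the list alone; camera adjusted p = 0.54 with an estimated correlation), with TT19 at 2.45 ± 0.56.

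In the eil1-labelled shoots 5 loci passed the interaction test, among them ERF6, an ethylene-response transcription factor (1.77 ± 0.26), and SPL4, a regulator of flowering (-1.34 ± 0.20). Both lost their call without Col-0 +S replicates 1 or 3 or the eil1-labelled -S replicate 3, ERF6 also without the eil1-labelled -S replicate 1 and SPL4 without the eil1-labelled +S replicate 2. ERF6 also lost it with only the groups compared in the fit. The count depended on single libraries: it was 0 without Col-0 +S replicate 1, Col-0 +S replicate 3 or the eil1-labelled -S replicate 3, by the edgeR test. It was 13 and 2 without Col-0 -S replicates 1 and 2, 27 and 2 without the eil1-labelled +S replicates 1 and 2, and 1 without the eil1-labelled -S replicate 1. The low-sulfate count of the eil1-labelled shoots was 3782 without -S replicate 3. The interaction count of the eil3-labelled shoots was 253 without Col-0 +S replicate 3, 244 and 234 without Col-0 -S replicates 1 and 3, and 203 and 198 without the eil3-labelled -S replicates 2 and 3.

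Scaling by total counts moved the balance of directions in shoots. The low-sulfate response had 4148 higher and 2043 lower loci in the eil1-labelled shoots (against 3127 and 2790), 8837 and 1636 in the eil3-labelled shoots (against 3917 and 3599) and 9169 and 4535 in the eil3 eil1-labelled shoots (against 7057 and 6141). The medians of all loci shifted by 0.25 in the eil3-labelled and 0.19 in the eil3 eil1-labelled shoots. The eil3-labelled interaction had 442 positive and 161 negative loci, against 162 and 224, with a shift of 0.12. Iron deficiency genes in Col-0 shoots, nitrate and methionine genes in the eil3-labelled shoots, and indolic glucosinolate genes in the eil3 eil1-labelled shoots, had list medians whose sign turned with this scaling.

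**Figure D4:**
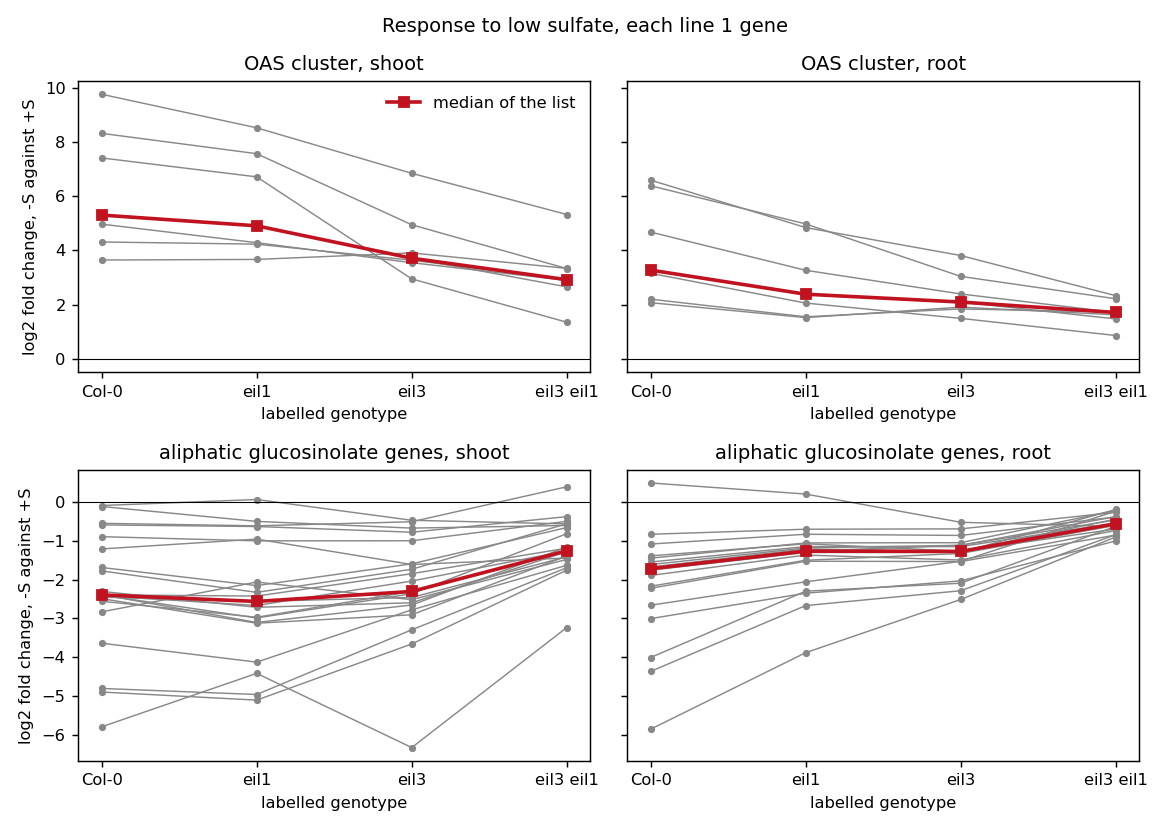
Log2 fold change at -S against +S of each OAS cluster gene (top) and aliphatic glucosinolate gene (bottom) in shoots (left) and roots (right), by labelled genotype. Grey lines join the values of 1 gene and red squares are list medians. In roots the OAS cluster median falls from 3.27 in Col-0 to 1.71 in the eil3 eil1-labelled genotype.

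Set against Col-0 at -S, jasmonate genes were lower for all 13 members in the eil3-labelled and for all 13 in the eil3 eil1-labelled shoots (13 and 13 adjusted over the list alone), and both camera calls held with an estimated correlation. These comparisons share the Col-0 -S libraries, so part of what they have in common may come from those libraries. LOX2 stood at 548 ± 97.7 and 357 ± 52.8 CPM, against 2125 ± 124 in Col-0, and TAT3 was lower by -1.48 ± 0.21 and -3.19 ± 0.23. Sulfate transporters were lower for 7 and 8 of 11 and higher for 2 and 1 (the same counts adjusted over the list alone), with SULTR1;1 (AT4G08620) at -2.49 ± 0.26 and -4.45 ± 0.30. SIR, sulfite reductase, was lower by -0.98 ± 0.10 and -1.24 ± 0.10, and NAP, a NAC regulator of senescence, by -1.96 ± 0.20 and -3.57 ± 0.22. BGLU28 was lower by -4.43 ± 0.31 and -7.71 ± 0.38. Root marker genes were lower in the eil3 eil1-labelled shoots for 7 of 9 (7 adjusted over the list alone; camera adjusted p = 0.414 with an estimated correlation), at a summed level of 2.49 ± 0.642 CPM against 11.4 ± 8.67 in Col-0, and against 6.45 in Col-0 without its -S replicate 3, which alone held 21.4. The counts of differing loci were 115 in the eil1-labelled, 3807 in the eil3-labelled and 11620 in the eil3 eil1-labelled shoots. Scaling by total counts gave 4042 higher and 937 lower loci in the eil3-labelled shoots, against 1921 and 1886, and 7617 and 4280 in the eil3 eil1-labelled shoots, against 5952 and 5668, with shifts of 0.13 and 0.11.

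The eil1-labelled shoots at -S had lower CYP83B1 (-0.86 ± 0.15) and APK1, an adenosine phosphosulfate kinase (-0.94 ± 0.15), than Col-0. No OAS cluster gene passed over all loci, and 6 of 7 were lower adjusted over the list alone. The eil1-labelled count at -S was 30, 59 and 9 without Col-0 -S replicates 1, 2 and 3, and 4, 4 and 290 without the eil1-labelled -S replicates 1, 2 and 3. The eil3-labelled count at -S was 2407 without Col-0 -S replicate 1, and 2501 and 1945 without the eil3-labelled -S replicates 2 and 3. Both genes lost their call without Col-0 -S replicate 3 or the eil1-labelled -S replicates 1 or 2, and CYP83B1 also without Col-0 -S replicate 1. APK1 lost its call with only the groups compared in the fit.

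At +S, OAS cluster genes were already higher than in Col-0 in the eil3-labelled shoots for 5 of 7 members and in the eil3 eil1-labelled shoots for 6 of 7 (6 and 7 adjusted over the list alone), and both camera calls held with an estimated correlation. LSU1 was higher by 2.53 ± 0.32 and 3.51 ± 0.31, and SULTR4;2 (AT3G12520) by 0.84 ± 0.13 and 1.32 ± 0.13. Indolic glucosinolate genes were lower in the eil1-labelled, eil3-labelled and eil3 eil1-labelled shoots for 6, 6 and 5 of 12 (11, 9 and 9 adjusted over the list alone), and 1 member was higher in the eil3 eil1-labelled shoots. CYP83B1, a cytochrome P450 of this pathway, differed by -0.92 ± 0.15, -1.15 ± 0.15 and -1.22 ± 0.15. With only the groups compared in the fit, CYP83B1 lost its call in the eil1-labelled and eil3-labelled shoots, and LSU1 and SULTR4;2 lost theirs in the eil3-labelled shoots. The list's camera call held in the eil1-labelled shoots (adjusted p = 0.0135 with an estimated correlation) and was lost in the others (adjusted p = 0.089 and 0.0617 with an estimated correlation). Salicylate defence genes were lower for 1, 6 and 8 of 12 (8, 11 and 8 adjusted over the list alone; camera adjusted p = 0.292, 0.349 and 0.251 with an estimated correlation). EDS1, a regulator of defence, stood at 30.3 ± 12.4 CPM in Col-0, 16.7 ± 1.31 in the eil3-labelled and 17.96 ± 2.84 in the eil3 eil1-labelled shoots (log2 -0.86 ± 0.19 and -0.76 ± 0.18). Both EDS1 calls were lost without Col-0 +S replicate 1 and with only the groups compared in the fit, and the eil3 eil1-labelled one also without that genotype's +S replicate 1, without its +S replicate 2 and with limma-trend. The 3 Col-0 libraries are shared by these comparisons, so part of what they have in common may come from those libraries.

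The counts at +S were 273, 1548 and 1636 loci in the eil1-labelled, eil3-labelled and eil3 eil1-labelled shoots. The eil1-labelled count was 35, 589 and 143 without Col-0 +S replicates 1, 2 and 3, and 145, 114 and 45 without the eil1-labelled +S replicates 1, 2 and 3. The eil3-labelled count was 606 and 1018 without Col-0 +S replicates 1 and 3, and 892 and 830 without the eil3-labelled +S replicates 1 and 2. The eil3 eil1-labelled count was 758 without Col-0 +S replicate 1, and 788 and 921 without its own +S replicates 1 and 2. With only the groups compared in the fit, the 3 counts were 14, 21 and 516. Scaling by total counts gave 107 higher and 59 lower loci in the eil1-labelled shoots (against 90 and 183), 600 and 733 in the eil3-labelled shoots (against 537 and 1011) and 1052 and 546 in the eil3 eil1-labelled shoots (against 617 and 1019).

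At -S the eil3 eil1-labelled libraries differed from the eil3-labelled ones in both targeted transcripts, so their differences cannot be read as those of EIL1 alone. In shoots, EIL1 was lower by -1.81 ± 0.082 and EIL3 higher by 0.65 ± 0.11, and in roots by -1.43 ± 0.10 and 0.52 ± 0.10. The EIL3 call in roots was lost without the eil3 eil1-labelled -S replicate 1 and with only the groups compared in the fit. Sulfate transporters were lower for 8 of 11 (8 adjusted over the list alone; camera adjusted p = 0.236 with an estimated correlation), photosynthesis genes for 14 of 17 (15; adjusted p = 0.266 with an estimated correlation), and aliphatic glucosinolate genes were higher for 17 of 21 (17; adjusted p = 0.37 with an estimated correlation). SULTR1;1 (AT4G08620) differed by -1.96 ± 0.30, LHCB3 by -1.26 ± 0.15 and IPMI-LSU1, an isopropylmalate isomerase subunit, by 0.72 ± 0.067. In roots, aliphatic glucosinolate genes were higher for 17 of 19 (18 adjusted over the list alone) and OAS cluster genes lower for 4 of 7 (5 adjusted over the list alone), and both camera calls held with an estimated correlation. BCAT4 was higher by 1.49 ± 0.14, ATPS4 by 0.83 ± 0.088, and SDI1 differed by -1.03 ± 0.18. The counts were 8270 loci in shoots and 351 in roots. The root count was 150 without the eil3-labelled -S replicate 1 and 151 without the eil3 eil1-labelled -S replicate 1.

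The low-sulfate responses of different genotypes overlapped. Of 3677 loci that rose in Col-0 shoots, 2295 rose in the eil1-labelled, 2334 in the eil3-labelled and 2421 in the eil3 eil1-labelled shoots, where independent lists of these sizes would share 529.9, 664 and 1196. Of 935 loci that rose in Col-0 roots, 188, 75 and 133 rose in the same genotypes, against 10.2, 4.39 and 20.6 for independent lists. These responses share no libraries between genotypes. The loci that rose in Col-0 roots had a median change of 0.47 there and of 0.19, 0.14 and 0.09 in the eil1-labelled, eil3-labelled and eil3 eil1-labelled roots. In shoots the corresponding medians were 0.50, 0.36, 0.37 and 0.47. The loci that fell in Col-0 had medians of -0.46, -0.18, -0.12 and -0.07 in roots and of -0.49, -0.33, -0.39 and -0.51 in shoots, in the same order of genotypes. Choosing loci by their change in Col-0 favours a larger median there.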

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

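The tests of explanations in this part were chosen after seeing results. EIL1 transcript was not reduced in the eil1-labelled libraries as it was in the eil3 eil1-labelled ones. The eil1-labelled libraries were unlike the Col-0 libraries in AT5G35935, at least 24.87 CPM against at most 3.631, so the same Col-0 plants under an eil1 label are excluded. The locus was picked from these data and was at least 24.87 CPM in every mutant-labelled genotype. It therefore cannot show whether the eil1-labelled plants carried an eil1 insertion. No library under a Col-0 or eil3 label held EIL1 as low as the eil3 eil1-labelled ones. The lowest under those labels was 83.8 percent of the Col-0 mean, and the highest in the eil3 eil1-labelled libraries 46.98 percent. This level alone does not exclude an exchange of eil1 with those labels, since an eil1 library that keeps EIL1 reads would not stand out by it. An exchange of eil1 with eil3 eil1 labels cannot be told apart from correct labels by the targeted transcripts. EIL3 was not reduced in the eil3 eil1-labelled libraries, and in roots it differed from the eil1-labelled ones by at most log2 -0.1323 (SE 0.0997). In shoots EIL3 was higher in the eil3 eil1-labelled than in the eil1-labelled libraries. The difference was log2 0.73 at +S and 0.33 at -S (edgeR adjusted p = 0.000759 and 0.0129). It does not decide either, since EIL3 in the eil3-labelled shoots did not differ from Col-0 (edgeR adjusted p = 0.94 and 0.226). Of 610 shoot loci that differed from Col-0 the same way at both sulfate levels in the eil3-labelled libraries, 319 did so also in the eil3 eil1-labelled alone and 3 in the eil1-labelled alone, and of 203 root loci 44 and 20. These counts do not decide about the labels, since the lists they draw on differ in size. In shoots 273 loci at +S and 115 at -S differed from Col-0 in the eil1-labelled libraries, against 1636 and 11620 in the eil3 eil1-labelled ones. In roots these were 272 and 551, against 193 and 2651. All comparisons also use the same Col-0 libraries, and the effect of both mutations together need not contain that of 1. Reads of paralogs are excluded as the whole signal, since EIL1 fell to 44.68 percent or less, and to 25.66 percent at the lowest, in eil3 eil1-labelled groups. A T-DNA line that keeps reads of part of EIL1 remains a hypothesis that locus counts cannot test. AT2G27060, which starts 2412 bases after EIL1, was 2.755 times the Col-0 level at -S and 2.182 times at +S in the eil1-labelled shoots (edgeR adjusted p = 5.17e-07 and 4.75e-05). In the eil3 eil1-labelled shoots it was 1.023 and 1.283 times the Col-0 level (adjusted p = 0.838 and 0.0718 by edgeR), and lower than in the eil1-labelled shoots by log2 -1.43 and -0.77 (edgeR adjusted p = 3.68e-09 and 0.00101). AGO4 (AT2G27040), which has a locus number next to that of EIL1, was 1.406 times the Col-0 level at -S and 1.507 times at +S in the eil1-labelled shoots (edgeR adjusted p = 0.0585 and 0.0148). In the eil3 eil1-labelled shoots AGO4 was 0.9976 and 1.119 times that level (edgeR adjusted p = 0.983 and 0.467). It did not pass in the eil1-labelled roots (edgeR adjusted p = 0.959 and 0.413). MAF5 was 7.391 and 9.852 times the Col-0 level in the eil1-labelled shoots, 5.401 and 6.541 times in the eil3-labelled and 0.5641 and 0.429 times in the eil3 eil1-labelled shoots. These AT2G27060 and MAF5 calls in shoots held with each library of the groups compared left out. In roots MAF5 did not pass the edgeR threshold between the eil3 eil1-labelled and eil1-labelled libraries (adjusted p = 0.678 at -S and 0.922 at +S), and AT2G27060 in the eil1-labelled roots was 1.178 and 1.128 times the Col-0 level (edgeR adjusted p = 0.321 and 0.521). Between the eil3 eil1-labelled and eil1-labelled roots it differed at -S by log2 -0.61 (edgeR adjusted p = 0.00105), a call that held with each library left out. At +S its edgeR adjusted p was 0.102, and 0.0447 without the eil1-labelled +S replicate 3. So in shoots the single lines and the double mutant differed at loci other than the 2 targeted ones, and whether they carry the same eil1 allele was left open. Until that is known, a value of a single line set against the double mutant has no assigned gene.

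The eil3 eil1-labelled shoots had the largest difference in response, at 8009 loci. The count did not depend on the TMM factors, with 7984 loci under total-count scaling. An error that both scalings share is not excluded, because low sulfate changed 13198 of 21697 loci in these shoots. A single deviating library is excluded, with at least 7019 loci when 1 was left out. Root tissue in the eil3 eil1-labelled -S shoots is excluded as the cause, with a median of -2.556 for the root marker list against Col-0, and of -1.638 without Col-0 -S replicate 3, whose summed level of 21.411 CPM stood apart from 5.7078 and 7.1929. The members are near the floor in these shoots, at a sum of at most 3.1952 CPM per library, against a mean of 410.027 in the roots of the same genotype at -S. No biological explanation was tested. The lists did not move as in a uniformly stronger response to low sulfate, since 8 of 11 sulfate transporters had a negative interaction and 14 of 21 aliphatic glucosinolate genes, of which 19 fell in Col-0, a positive one.

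AT5G35935, MRD1 and HEI10 differed between Col-0 and every mutant-labelled genotype. Single deviating Col-0 libraries are excluded for AT5G35935. The highest of 12 Col-0 libraries held 3.631 CPM and the lowest of 36 others 24.87. The locus was picked from these data for differing in all comparisons with Col-0. A deviation common to the Col-0 libraries would give the same gap and is not excluded. For AT5G35935 a background shared by the mutant lines could not be told apart from other causes, with a range of 0.1876 between genotypes in its difference. This range was not tested for MRD1 and HEI10, whose differences were less alike in -S shoots. In the eil1-labelled, eil3-labelled and eil3 eil1-labelled shoots MRD1 differed by log2 -3.11 ± 0.649, -6.99 ± 0.903 and -2.33 ± 0.617. HEI10 differed by -1.61 ± 0.255, -1.60 ± 0.255 and -0.69 ± 0.245. In -S roots HEI10 differed by -1.14, -1.01 and -1.27.

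The other results were tested as interactions. In shoots the response differed from Col-0 at 5 loci in the eil1-labelled and 386 in the eil3-labelled libraries, and in roots at 84, 207 and 840 loci in the eil1-labelled, eil3-labelled and eil3 eil1-labelled libraries. The organs differed at 2948 loci.

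Libraries were also regrouped, with only the groups compared in the fit. For comparisons of 3 against 3 libraries the 10 splits are too few for a share under 0.05. In shoots the real low-sulfate counts were 6767, 6147, 4947 and 12586, and the highest other splits gave 0, 1, 0 and 0. Against Col-0 at -S they were 106, 3713 and 11334, with 1, 0 and 0, and at +S 14, 21 and 516, with 1, 1 and 0. In roots the low-sulfate counts were 1367, 262, 102 and 916, with 0, 0, 0 and 7. Against Col-0 at -S they were 277, 1155 and 2362, with 0, 1 and 0, and at +S 135, 250 and 325, with 5, 1 and 0. The eil3 eil1-labelled against eil3-labelled counts were 8007 in shoots and 200 in roots, with 0 and 0. In each of these 1 split, the real one, was as large.

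For interactions 100 splits were drawn. In shoots 3, 4 and 2 splits were as large as the real counts of 3, 143 and 7835, with 9576, 8301 and 8854 as the highest others. In roots 3, 5 and 1 were as large as 41, 173 and 905, with 1474, 720 and 836. For the organ difference 1 was as large as 2948, with 922 as the highest other. Splits with several times the real count point to a structure of samples, because regrouping can turn a difference of sulfate or genotype into an interaction. Such splits are no measure of chance, so the share of 5 in 100 for the eil3-labelled roots does not decide about it. There the camera calls of the OAS cluster and of sulfate transport held with an estimated correlation (adjusted p = 2.06e-05 and 4e-05).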

How the results depend on the processing

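Total-count scaling was chosen after seeing the data, and the other settings before it. Counts are loci past the threshold, genotypes are as labelled, and the cause of each difference was not tested. Limma-trend on TPM gave 12419 for eil3 low-sulfate response in shoots, 52 for eil1 at -S in shoots, 113 for eil1 at +S in shoots, 852 for eil3 at +S in shoots and 13 for eil1 interaction in shoots. It also gave 701 for eil3 interaction in shoots. Only the groups compared in the fit gave 4947 for eil3 low-sulfate response in shoots, 14 for eil1 at +S in shoots, 21 for eil3 at +S in shoots, 516 for eil3 eil1 at +S in shoots and 3 for eil1 interaction in shoots. It also gave 143 for eil3 interaction in shoots, 262 for eil1 low-sulfate response in roots, 102 for eil3 low-sulfate response in roots, 277 for eil1 at -S in roots and 135 for eil1 at +S in roots. It also gave 250 for eil3 at +S in roots, 325 for eil3 eil1 at +S in roots, 41 for eil1 interaction in roots and 200 for eil3 eil1 against eil3 at -S in roots. Total-count scaling gave 76 for eil1 at -S in shoots, 166 for eil1 at +S in shoots, 9 for eil1 interaction in shoots and 603 for eil3 interaction in shoots. DESeq2 gave 527 for eil1 at -S in shoots, 682 for eil1 at +S in shoots, 109 for eil1 interaction in shoots, 804 for eil3 interaction in shoots and 415 for eil3 low-sulfate response in roots. It also gave 863 for eil1 at -S in roots, 572 for eil1 at +S in roots, 828 for eil3 at +S in roots, 467 for eil3 eil1 at +S in roots and 198 for eil1 interaction in roots. It also gave 409 for eil3 interaction in roots and 662 for eil3 eil1 against eil3 at -S in roots. RLE size factors gave 10 for eil1 interaction in shoots. No low-count filter gave 20 for eil1 interaction in shoots. A replicate block in roots, where 15 of 24 libraries matched best with their own number, gave 349 for eil3 eil1 at +S in roots. With 1 library left out in turn, counts ranged from 3782 to 5360 for eil1 low-sulfate response in shoots, 4 to 290 for eil1 at -S in shoots, 1945 to 3646 for eil3 at -S in shoots and 35 to 589 for eil1 at +S in shoots. They ranged from 606 to 2132 for eil3 at +S in shoots, 758 to 1693 for eil3 eil1 at +S in shoots, 0 to 27 for eil1 interaction in shoots and 198 to 554 for eil3 interaction in shoots. They ranged from 238 to 471 for eil1 low-sulfate response in roots, 142 to 187 for eil3 low-sulfate response in roots, 477 to 744 for eil3 eil1 low-sulfate response in roots and 187 to 592 for eil1 at -S in roots. They ranged from 938 to 1408 for eil3 at -S in roots, 52 to 398 for eil1 at +S in roots, 110 to 389 for eil3 at +S in roots and 65 to 147 for eil3 eil1 at +S in roots. They ranged from 37 to 101 for eil1 interaction in roots, 526 to 934 for eil3 eil1 interaction in roots and 150 to 296 for eil3 eil1 against eil3 at -S in roots. EIL1 in eil1-labelled roots at +S, which did not differ from Col-0, turned to -0.0040482 with total-count scaling, -6.46e-06 with the block, and lay between -0.018383 and 0.036574 with 1 library left out. Of the named gene values, 10 of 144 lost their call with only the groups compared and 2 of 150 with limma-trend, and 1 of 150 gained it with DESeq2, EIL1 in eil1-labelled shoots at +S.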

Other observations

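The tests in this part were chosen after seeing the data. A single locus (1) was higher than Col-0 in all 6 comparisons of shoots, 3 in all 6 of roots and 1 in both, where independent organs would share 0.000145. Lower in all 6 were 11 in shoots, 10 in roots and 2 in both, where 0.00533 would be shared. Both organs came from the same lines, so independent organs are only a reference for the overlap. The 2 loci lower in both, MRD1 (AT1G53480) and HEI10 (AT1G53490), have neighbouring locus numbers and need not be independent. Simulated libraries with no effect gave 0 such loci in each organ and direction. They held no genotype effect and no deviation common to the Col-0 libraries, so this 0 cannot decide why loci are shared over comparisons. MRD1 was 33.28 to 53.49 CPM in Col-0 libraries and 0 to 7.687 in the others. HEI10 libraries overlapped, at 3.965 to 11.03 CPM in Col-0 and 1.265 to 7.182 in the others. AT5G35935 was 0.1271 to 3.631 CPM in Col-0 and 24.87 to 38.7 in the others.

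In roots, without the eil1-labelled +S replicate 1, whose photosynthesis sum stood apart, the eil1-labelled comparison with Col-0 at +S had 83 loci, 50 higher and 33 lower. Its interaction then had 61 loci, 27 positive and 34 negative. Without Col-0 +S replicate 1 the same comparisons had 398 and 89 loci.

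Of 522 list tests 228 passed camera with the preset correlation, and 82 of these with the estimated correlation.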
